A study of Mus musculus with 20 samples.

How the data were processed

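RNA of the heart apex was sequenced from 20 wild-type FVB/NRj mice at postnatal day 28, in 4 groups of 5 mice. The groups were set by the sample labels: a CMV control, CMV Zeb2os, an hTNNT2 control and hTNNT2 Zeb2os. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library preparation. Per the submitters' processing notes, the authors trimmed reads with Trim Galore, used the genome builds GRCm38 and mm10, and compared groups with DESeq2. The aligner, the read counter, its strand setting and all tool versions are not given in the sources used here.

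Each promoter had a deposited table of the authors' own comparison of Zeb2os with its control, with 26214 genes listed in both. Per the file headers, the mean normalised count of a gene over the 10 libraries of a comparison was deposited as a signal that cannot be negative. The authors' fold changes and their standard errors were deposited on the log2 scale. The deposited Wald statistic is a score, and the p-value and the adjusted p-value were deposited beside it by the authors. The deposited statistic had the opposite sign to the log2 fold change in each row, so it was turned to be positive where a gene was higher with Zeb2os. The deposited p-value was checked to be the 2-sided normal p of the deposited statistic. Benjamini-Hochberg adjustment of the deposited p-values gave the authors' adjusted p-values to within 0.000274 in the CMV table.

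A p-value stood beside 21318 genes in the CMV table and 21461 in the hTNNT2 table deposited by the authors. In the table deposited for hTNNT2, a total of 3292 genes had a p-value and no adjusted p-value, and their mean counts reached at most 1.86. A statistic without a p-value was listed for 7 genes in the deposited CMV table and 14 in the deposited hTNNT2 table, and these genes were left out of every test. The total count of each library is not given in the sources used here. Mean normalised counts summed to 44295571 in the CMV table and 51284505 in the hTNNT2 table of the authors, and the 2 tables were normalised separately. Values of single mice were not used here, so no spread between mice was computed, and sex could not enter a model.

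The tests were fixed before the data were examined, with the case foreseen that tables would hold only the authors' comparisons. A gene counted as changed where the authors' adjusted p-value was under 0.05. The difference between promoters was the hTNNT2 log2 fold change minus the CMV log2 fold change, divided by the root of the summed squared standard errors. Its 2-sided normal p was adjusted by the Benjamini-Hochberg method over the 20754 genes tested in both tables. Gene lists comprised 23 pathway lists and 18 lists of cell type markers, and 655 of their 677 entries matched a gene of the tables, older symbols included. Of the lists, 40 had at least 2 members with a p-value. They were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the Wald statistic, against all other genes with a p-value. The preset correlation between genes was 0.01, and p-values were adjusted over the 40 lists of a comparison. An estimated correlation needs values per mouse, so for each list the correlation at which its unadjusted p would reach 0.05 was computed instead. Calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

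Named genes followed a rule fixed at the same time. It took Zeb2os and Zeb2, then up to 10 genes in each direction with the largest log2 fold change among changed genes with a mean count of at least 50. Predicted genes and genes of the Y chromosome were left out, as were Xist and Tsix. It also took up to 4 changed members of each list, or up to 2 members as values where none changed, and the 10 clearest differences between promoters. Not every gene taken by this rule is reported here. Genes named outside this rule are marked as chosen after their values were seen. Coordinates, transcript lengths and GC content came from GENCODE release M21 on GRCm38. Of genes with a mean count of at least 50, 97.6% in each table had a length and GC content. The check of length and GC content is void for the list of histone genes, where fewer members had these values.

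The difference test and the list test were tested on simulated data. With standard errors as deposited for 20754 genes, 68% of 100 genes simulated with a log2 difference of 0.4 between promoters were called, and 100% of 100 genes with 0.8. Of the 176 simulated calls, 4.55% were unchanged genes. Lists shifted by 1 in the statistic were called in 92% of 100 simulated cases, and unshifted lists in 0.333% of 600. The simulated genes were independent of each other, so this says nothing of genes that vary together between mice. Simulated differences lay on the deposited scale, so these rates do not carry over to changes on another scale. The simulated statistics had a spread of 1. The deposited ones had a robust spread of 0.81 (CMV) and 0.93 (hTNNT2) among genes with a mean count of at least 50. The alternatives comprised other thresholds, minimum mean counts of 10 and 50, other sets of genes for the adjustment, centring on the median gene and an empirical null. For lists they were a correlation of 0.05, ranks, log2 fold changes in place of the statistic and, chosen after the data were examined, removal of Zeb2os and of trends with mean count, transcript length and GC content.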

Results

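RNA-seq was carried out on the heart apex of 20 uninjured wild-type mice at postnatal day 28. The mice had received AAV9, a viral vector that reaches the heart well, through the retro-orbital vein. The vector carried either Zeb2os, the long noncoding RNA transcribed antisense to Zeb2, or a control. The cargo was driven by the CMV promoter, active in most cell types, or by the hTNNT2 promoter of cardiac troponin T, active in cardiomyocytes. Each of the 4 groups held 5 mice. Sex differed between arms. The CMV control group had 2 males and the CMV Zeb2os group 1, whereas the hTNNT2 control group had 0 males and the hTNNT2 Zeb2os group 3. Values came from the authors' comparisons of 5 with 5 mice, so each gene has a log2 fold change with its standard error (SE) and no value per mouse. The total count per library is not given in the sources used here.

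The first question was whether Zeb2os RNA rose with the vector and whether Zeb2, the zinc-finger transcription factor on the opposite strand, moved with it. With the CMV promoter, Zeb2os rose in the authors' deposited table by a log2 fold change of 3.66 (SE 0.071), a fold of 12.7. With the hTNNT2 promoter it rose by 4.53 (SE 0.083), a fold of 23.1 in the authors' deposited table. The adjusted p-value was listed as 0 in both. Mean normalised counts of Zeb2os over the 10 libraries were 4138 in the authors' deposited table for CMV and 43281 in the one for hTNNT2. That is a ratio of 10.5 between tables normalised separately, where the median gene with a mean of at least 50 had a ratio of 1.16. Zeb2 did not pass the test in either of the authors' deposited tables. Its log2 fold change was -0.0095 (SE 0.059, adjusted p = 1) with CMV and 0.033 (SE 0.080, adjusted p = 1.00) with hTNNT2 in the authors' deposited tables. The 95% intervals from the deposited SE ran from -0.13 to 0.11 and from -0.12 to 0.19 in the authors' deposited tables. The median SE of the authors' deposited tables was 0.0054 (CMV) and 0.0073 (hTNNT2) below a mean count of 0.5, against 0.068 and 0.078 at 200 to 1000. An SE that falls with the count is not that of a plain ratio of counts, so the folds and intervals above hold on the deposited scale alone and do not limit a change on another scale. In GENCODE M21 on GRCm38, Zeb2os lies on the plus strand of chromosome 2 from 45110707 to 45114087, inside Zeb2, which runs on the minus strand from 44983632 to 45117395. Of its 1990 exonic bases, 653 (32.8%) overlap exons of Zeb2. The strand setting of the counting is not given in the sources used here, so reads of this overlap cannot be assigned with certainty.

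Thymosin beta 4 and prothymosin alpha, paracrine factors known as products of Zeb2 activity, were followed with thymosin beta 10. Of these 3 measured genes, 0 passed in either of the authors' deposited tables, with 0 also at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Tmsb4x had a log2 fold change of 0.13 (SE 0.079) and Ptma of -0.0016 (SE 0.081) with hTNNT2 in the authors' deposited table. The corresponding values with CMV were 0.028 (SE 0.071) and -0.052 (SE 0.069) in the authors' deposited table. Fetal and dedifferentiation genes, which mark a return of heart muscle cells to an immature state, did not shift as a list. The adjusted p of cameraPR was 0.313 with CMV and 0.418 with hTNNT2. Of 25 and 23 measured members, 0 rose or fell over all genes in the authors' deposited tables, and 1 fell in each when adjusted over the list alone. These were Runx1 with CMV, at -0.22 (SE 0.071), and Hand2 with hTNNT2, at -0.25 (SE 0.077), in the authors' deposited tables. At an unadjusted p under 0.05, 1 was lower with CMV, and 3 were higher and 4 lower with hTNNT2.

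**Figure D1:**
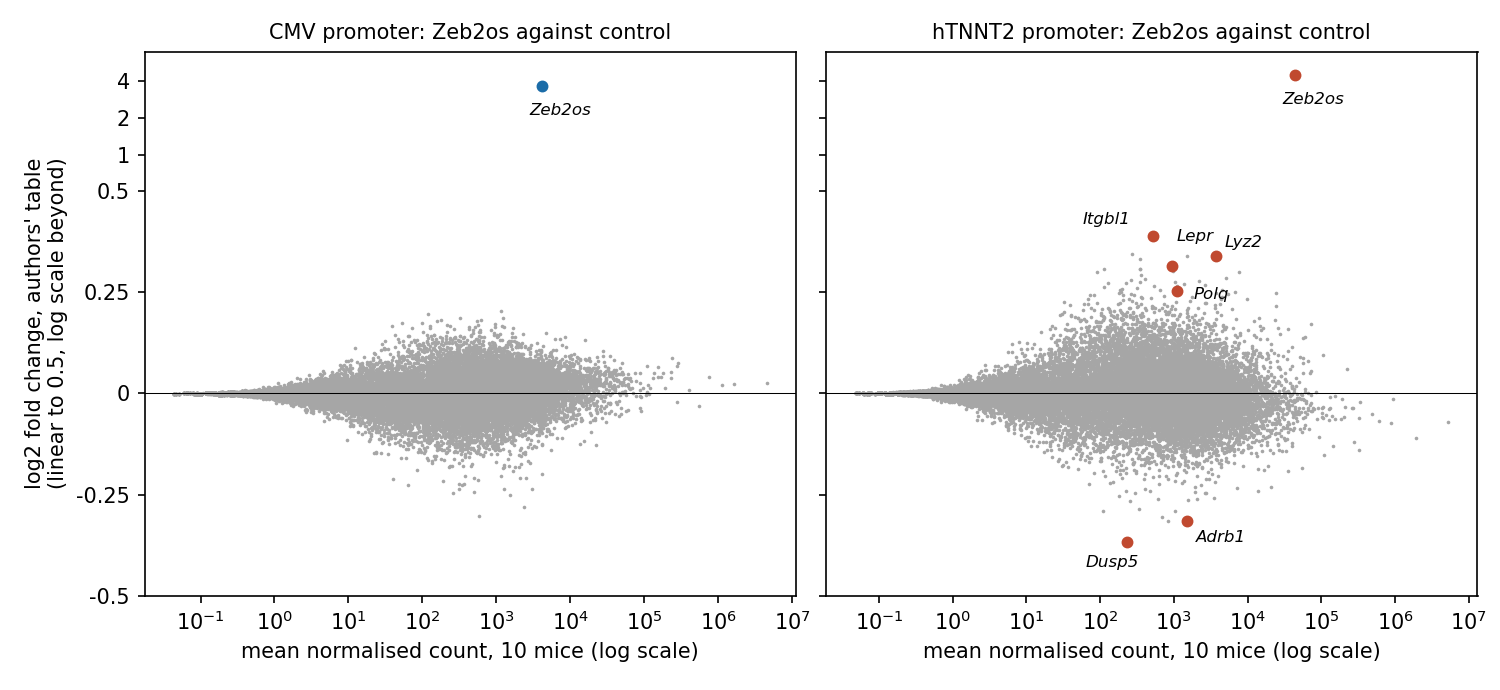
Log2 fold change of Zeb2os against control from the authors' deposited tables (y axis, linear to 0.5 and logarithmic beyond) against the mean normalised count over 10 mice (x axis, log scale), for the CMV and hTNNT2 promoters. Coloured, named points have an adjusted p under 0.05: 1 gene with CMV and 7 with hTNNT2.

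With the CMV promoter, Zeb2os was the single gene that changed at an adjusted p under 0.05 in the authors' deposited table. The nearest other gene, Enc1, an actin-associated protein singled out after its value was seen, had a log2 fold change of -0.30 (SE 0.066, adjusted p = 0.053) in the authors' deposited table. At an unadjusted p under 0.05 the authors' deposited table held 141 higher and 216 lower genes. Uniform p-values would give 1066 of 21318. The statistics of genes with a mean count of at least 50 had a robust spread of 0.81, however. Because that lies under the 1 that uniform p-values need, 1066 is not the number to expect by chance. Centring the fold changes on the median gene gave 1 higher and 1 lower gene. An empirical null, which rescales the statistics to their own spread, gave 1 higher and 12 lower.

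Among the 40 lists, 5 shifted with CMV Zeb2os. The number was 9 without Zeb2os and 10 with the trend in mean count removed, alternatives chosen after the data were examined. Immediate early genes, transcription factors and signalling genes switched on within minutes of stimulation, shifted downward (mean log2 fold change -0.098, adjusted p of cameraPR = 2.84e-13). Of 23 measured members, 21 were lower. Over all genes 0 fell in the authors' deposited table, 3 fell when adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05. These 3, of which Btg2 lay outside the naming rule and was added after its value was seen, were Nr4a1 at -0.14 (SE 0.044), Fosl2 at -0.21 (SE 0.071) and Btg2 at -0.19 (SE 0.065) in the authors' deposited table. Smooth muscle and pericyte markers also shifted downward, with 10 of 11 members lower and a mean of -0.062 (adjusted p of cameraPR = 0.0060). In the authors' deposited table Tagln stood at -0.14 (SE 0.071) and Notch3 at -0.10 (SE 0.052), neither passing, and 0 members passed over all genes, over the list alone or at an unadjusted p under 0.05.

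Nuclear-encoded subunits of the respiratory chain shifted upward with CMV Zeb2os, by a mean log2 fold change of 0.043 (adjusted p of cameraPR = 1.01e-05). Of 42 members, 40 were higher and 0 rose in the authors' deposited table, over all genes, over the list alone or at an unadjusted p under 0.05. Ndufs4 stood at 0.075 (SE 0.052) and Ndufs1 at 0.067 (SE 0.047) in the authors' deposited table. Sarcomere genes of the adult ventricle, which build the contractile apparatus, had 21 of 22 members higher, with a mean of 0.043 (adjusted p of cameraPR = 0.00162). The contractile proteins Myl2 and Tcap stood at 0.089 (SE 0.059) and 0.088 (SE 0.067) in the authors' deposited table. T and NK cell markers had 10 of 12 members higher, at a median mean count of 12.7 (mean log2 fold change 0.026, adjusted p of cameraPR = 0.0364). The statistic itself increased with the mean count across genes, which are not independent. Spearman's rho was 0.15 among genes with a mean count of at least 50 and 0.12 over all tested genes, Zeb2os left out. With that trend removed, sarcomere genes no longer passed (adjusted p of cameraPR = 0.223), and with length and GC content also removed neither did respiratory chain subunits (0.447). T and NK markers passed under 3 of 5 alternatives. They did not pass at a correlation of 0.05 (adjusted p of cameraPR = 0.11) or with log2 fold changes in place of the statistic (0.241). Immediate early genes would lose an unadjusted p under 0.05 at a correlation of 0.83 between members, and smooth muscle markers at 0.24. Respiratory chain subunits would lose it at 0.20, sarcomere genes at 0.17 and T and NK markers at 0.12.

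With the hTNNT2 promoter, 5 genes rose and 2 fell at an adjusted p under 0.05 in the authors' deposited table. Besides Zeb2os, Itgbl1, an integrin beta-like matrix protein, rose by a log2 fold change of 0.39 (SE 0.083, adjusted p = 0.0173) in the authors' deposited table. Lyz2, the lysozyme of macrophages and other myeloid cells, rose by 0.34 (SE 0.071, adjusted p = 0.0155) in the authors' deposited table. The leptin receptor Lepr rose by 0.31 (SE 0.069, adjusted p = 0.0222), and Polq, DNA polymerase theta, by 0.25 (SE 0.057, adjusted p = 0.0254), in the authors' deposited table. Dusp5, a phosphatase that inactivates ERK in the nucleus, fell by 0.37 on the log2 scale (SE 0.080, adjusted p = 0.0200) in the authors' deposited table. Adrb1, the beta-1 adrenergic receptor, fell by 0.32 on the log2 scale (SE 0.071, adjusted p = 0.0254) in the authors' deposited table. Itgbl1 lies on chromosome 14 (123659971 to 123975618), Lyz2 on chromosome 10 (117277331 to 117282321), Lepr on chromosome 4 (101717404 to 101815352) and Polq on chromosome 16 (37011786 to 37095417). Both genes that fell lie on chromosome 19, Dusp5 from 53529109 to 53542431 and Adrb1 from 56722199 to 56733113. At an unadjusted p under 0.05 the authors' deposited table held 488 higher and 353 lower genes. Uniform p-values would give 1073 of 21461, but the robust spread of the statistics was 0.93 here, again under 1. The empirical null gave 19 higher and 4 lower genes. Of the 7 genes, Zeb2os alone passed an adjusted p threshold of 0.01 in the authors' deposited table.

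In the same comparison 13 of 40 lists shifted, 8 upward and 5 downward. Markers of macrophages and monocytes shifted upward by a mean log2 fold change of 0.16 (adjusted p of cameraPR = 5.52e-11), with 12 of 13 members higher. Of these, 1 rose over all genes in the authors' deposited table and 6 when adjusted over the list alone. Beside Lyz2, and chosen after their values were seen, the mannose receptor Mrc1 stood at 0.26 (SE 0.074) and the growth factor receptor Csf1r at 0.21 (SE 0.069) in the authors' deposited table. Extracellular matrix and fibrosis genes shifted by a mean of 0.10 (adjusted p of cameraPR = 5.52e-11), with 31 of 33 members higher. Over all genes 0 rose in the authors' deposited table, 2 rose when adjusted over the list alone, and 9 were higher at an unadjusted p under 0.05. The matrix proteins Dcn and Thbs2 stood at 0.25 (SE 0.063) and 0.27 (SE 0.079) in the authors' deposited table. Fibroblast markers, 9 of 10 of them higher, shifted by a mean of 0.087 (adjusted p of cameraPR = 0.00109), and smooth muscle and pericyte markers, 10 of 11 higher, by 0.078 (0.00144). Over all genes 0 members of these lists rose in the authors' deposited table. Adjusted over the list alone, 1 fibroblast marker rose, Dcn again, and 0 smooth muscle markers. At an unadjusted p under 0.05, 3 fibroblast markers were higher, and 1 smooth muscle marker was higher and 1 lower. Cell cycle and mitosis genes had 31 of 33 members higher, with a mean of 0.072 (adjusted p of cameraPR = 1.59e-07). Over all genes and over the list alone 0 rose in the authors' deposited table, and 2 were higher at an unadjusted p under 0.05. Rrm2, which makes nucleotides for DNA replication, and Cdc20, an activator of mitotic exit, stood at 0.19 (SE 0.075) and 0.15 (SE 0.067) in the authors' deposited table. Endothelial markers did not pass, with 8 of 12 members higher and a mean of 0.011 (adjusted p of cameraPR = 0.598).

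Genes of heart muscle function lay on the other side. Sarcomere genes had 21 of 22 members lower, with a mean log2 fold change of -0.061 (adjusted p of cameraPR = 0.00301). Nebl, of the Z-disc, stood at -0.13 (SE 0.056) in the authors' deposited table. Calcium handling and ion channel genes had 17 of 22 members lower, with a mean of -0.058 (adjusted p of cameraPR = 0.00274). Here the calcium channel Cacna1g stood at -0.12 (SE 0.054) and the ryanodine receptor Ryr2 at -0.14 (SE 0.067) in the authors' deposited table. Cardiomyocyte markers, several of them also in those lists, had 8 of 9 members lower (mean -0.066, adjusted p of cameraPR = 0.0350). Over all genes 0 members of these lists fell in the authors' deposited table, and 0 over each list alone. At an unadjusted p under 0.05 1, 3 and 1 members were lower in turn. The unadjusted p of these lists would reach 0.05 at a correlation between members of 0.13, 0.14 and 0.10 in turn. With the trend across mean counts, transcript length and GC content removed, none of these 3 lists passed, at adjusted p of 0.177 for sarcomere genes, 0.144 for calcium handling and 0.198 for cardiomyocyte markers. Cardiomyocyte markers passed under 3 of 7 alternatives, with losses also at a correlation of 0.05 (adjusted p = 0.0912), at mean counts of at least 50 (0.0700) and with the mean count trend alone removed (0.187), where sarcomere genes lost the call too (0.0813).

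Of the lists of lymphoid cells, all measured at low counts, 2 shifted downward with hTNNT2 Zeb2os. Markers of B and plasma cells did not pass, with 7 of 7 members lower (adjusted p of cameraPR = 0.0692). Markers of T and NK cells had 9 of 12 members lower (mean log2 fold change -0.045, adjusted p of cameraPR = 0.0324). Markers of thymus and lymphoid organ had 6 of 6 lower (mean -0.046, adjusted p of cameraPR = 0.00389). Cd8a, a receptor of cytotoxic T cells, stood at -0.11 (SE 0.053) in the authors' deposited table. Histone-related genes were shifted upward (mean 0.083, 6 of 7 higher, adjusted p of cameraPR = 0.0102), as were ribosomal proteins (0.031, 28 of 40, 0.0324) and interferon response genes (0.037, 26 of 34, 0.0350). In these 5 lists 0 members passed over all genes in the authors' deposited table, and 1, a histone-related gene, rose when adjusted over the list alone. At an unadjusted p under 0.05, 1 T and NK marker was lower, and 1 histone-related gene, 3 ribosomal proteins and 2 interferon genes were higher. The histone list lost the call with the 3 trends removed (adjusted p = 0.344), a check that is void for it because too few members had a length and GC content. The other 4 lists lost the call under at least 1 alternative, where the highest adjusted p was 0.0912 for T and NK markers, 0.220 for thymus markers and 0.182 for both ribosomal proteins and interferon genes. The macrophage, matrix, fibroblast, smooth muscle and cell cycle lists passed under all 7 list alternatives. Their unadjusted p would reach 0.05 at a correlation between members of 0.51 for matrix genes, 0.36 for fibroblast markers, 0.30 for smooth muscle markers and 0.32 for cell cycle genes. Macrophage markers, at a mean statistic of 2.01, kept an unadjusted p under 0.05 at a correlation of 1. This p is not adjusted over the 40 lists, so it does not show at what correlation the adjusted call would be lost. The correlation at which the unadjusted p would reach 0.05 was 0.42 for thymus markers, 0.26 for histone-related genes and 0.093 for T and NK markers. It was only 0.038 for ribosomal proteins and 0.037 for interferon genes.

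**Figure D2:**
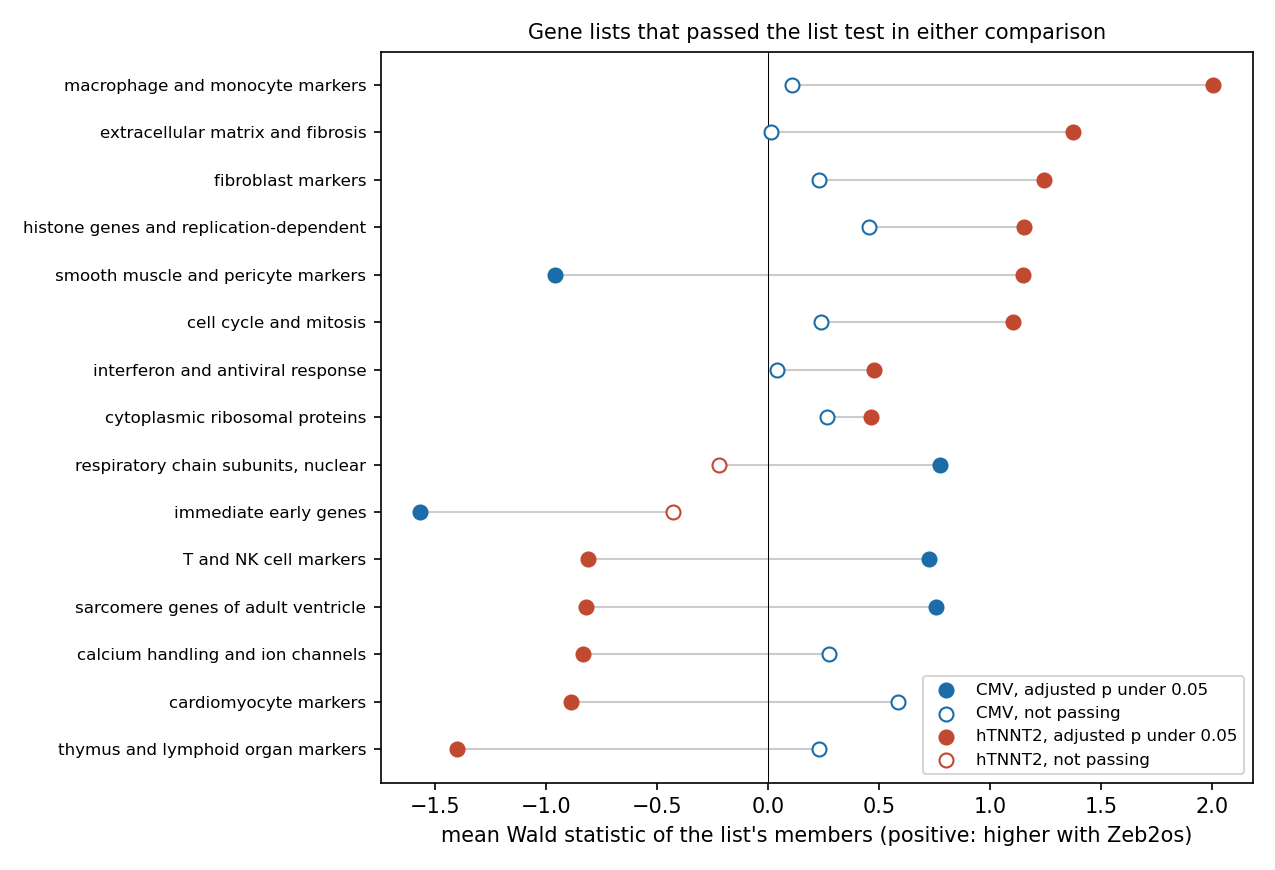
Mean Wald statistic of the members (x axis, no unit, positive where genes were higher with Zeb2os) of each gene list that passed cameraPR in either comparison (y axis), computed from the authors' deposited tables. Filled points have an adjusted p under 0.05, blue for CMV and red for hTNNT2. Macrophage markers reach 2.01 with hTNNT2, and immediate early genes -1.57 with CMV.

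The sex makeup of the arms could be followed in part in the tables. The X-linked genes Ddx3x, Kdm6a, Kdm5c and Eif2s3x, which escape X inactivation and so are higher in females, were chosen after values had been seen. With hTNNT2, where males were added, all 4 were lower, by a mean log2 fold change of -0.17 (p of cameraPR = 1.63e-05). With CMV, where the share of males was lower by 20 percentage points, all 4 were higher, by a mean of 0.044. That shift did not pass (p of cameraPR = 0.126), and 0 of the 4 had an unadjusted p under 0.05 with CMV. Of the 6 genes fixed as a sex check, 5 were higher with hTNNT2 and 5 lower with CMV, and 0 passed in the authors' deposited tables. These 5 were the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y, and the X-linked Tsix. Xist lay the other way, at -0.019 with hTNNT2 and 0.0022 with CMV in the authors' deposited tables. The Y-linked genes lay near 0, from 0.013 to 0.019 with hTNNT2 in the authors' deposited table. The difference in sex stands beside every hTNNT2 value above, because sex could not be separated from the cargo there.

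The pair of promoters was then compared directly. The male share was higher by 60 percentage points with hTNNT2 Zeb2os and lower by 20 with CMV Zeb2os. Sex could therefore not be separated from the promoter here. Of 20754 genes tested in both tables, the response of 1 differed at an adjusted p under 0.05 of the normal test of the difference. This was Zeb2os, whose log2 fold change was 0.87 (SE 0.11) larger with hTNNT2 in the authors' deposited tables. That difference holds on the deposited scale alone. Read as plain ratios, the folds would put Zeb2os in controls at mean counts of 606 (CMV) and 3594 (hTNNT2). These imply a ratio of 5.93 between controls of tables normalised separately. A difference of the Wald statistics, in place of the fold changes, gave 0 genes. The next was Polq, at 0.25 with hTNNT2 and -0.12 with CMV in the authors' deposited tables, a difference of 0.38 (SE 0.085, adjusted p = 0.0869). Across genes, the log2 fold changes of both tables had a Spearman correlation of 0.056 and a Pearson correlation of 0.27, the latter 0.048 without Zeb2os, and genes are not independent replicates. The single gene that rose in both of the authors' deposited tables was Zeb2os, the vector's own cargo in each, and 0 other genes were shared. Of 50 genes other than Zeb2os with an unadjusted p under 0.001 and a mean of at least 50, taken from the hTNNT2 comparison of the authors' deposited tables, 20 had the same sign with CMV. Of the 11 such genes in the authors' deposited CMV table, 9 had the same sign with hTNNT2. Among all genes with a mean of at least 50 in both, 52.6% had the same sign. An unadjusted p under 0.05 with the same sign in the other comparison was reached by 2 of the 50 and 1 of the 11.

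Of 40 lists, 14 passed the list test on the difference of the statistics. That test is unlike the one of single genes, so the counts of lists and genes cannot be set against each other. The 4 X-linked genes, chosen after values were seen, also differed, lower with hTNNT2 (p of cameraPR = 2.66e-06). Sex thus ran along this contrast, and no list difference can be assigned to the promoter alone. Macrophage markers differed by a mean of 0.15 on the log2 scale (adjusted p of cameraPR = 5.92e-07) and matrix genes by 0.10 (2.67e-07), both higher with hTNNT2. Smooth muscle and pericyte markers, lower with CMV and higher with hTNNT2, differed by 0.14 (adjusted p of cameraPR = 2.84e-07). Sarcomere genes differed by -0.10 in the other direction (adjusted p of cameraPR = 2.67e-07). The adjusted p was 0.0505 with the trends of mean count, length and GC content removed. Immediate early genes, lower in 21 of 23 members with CMV and 17 of 23 with hTNNT2, differed by 0.066 (adjusted p of cameraPR = 0.000195).

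**Figure D3:**
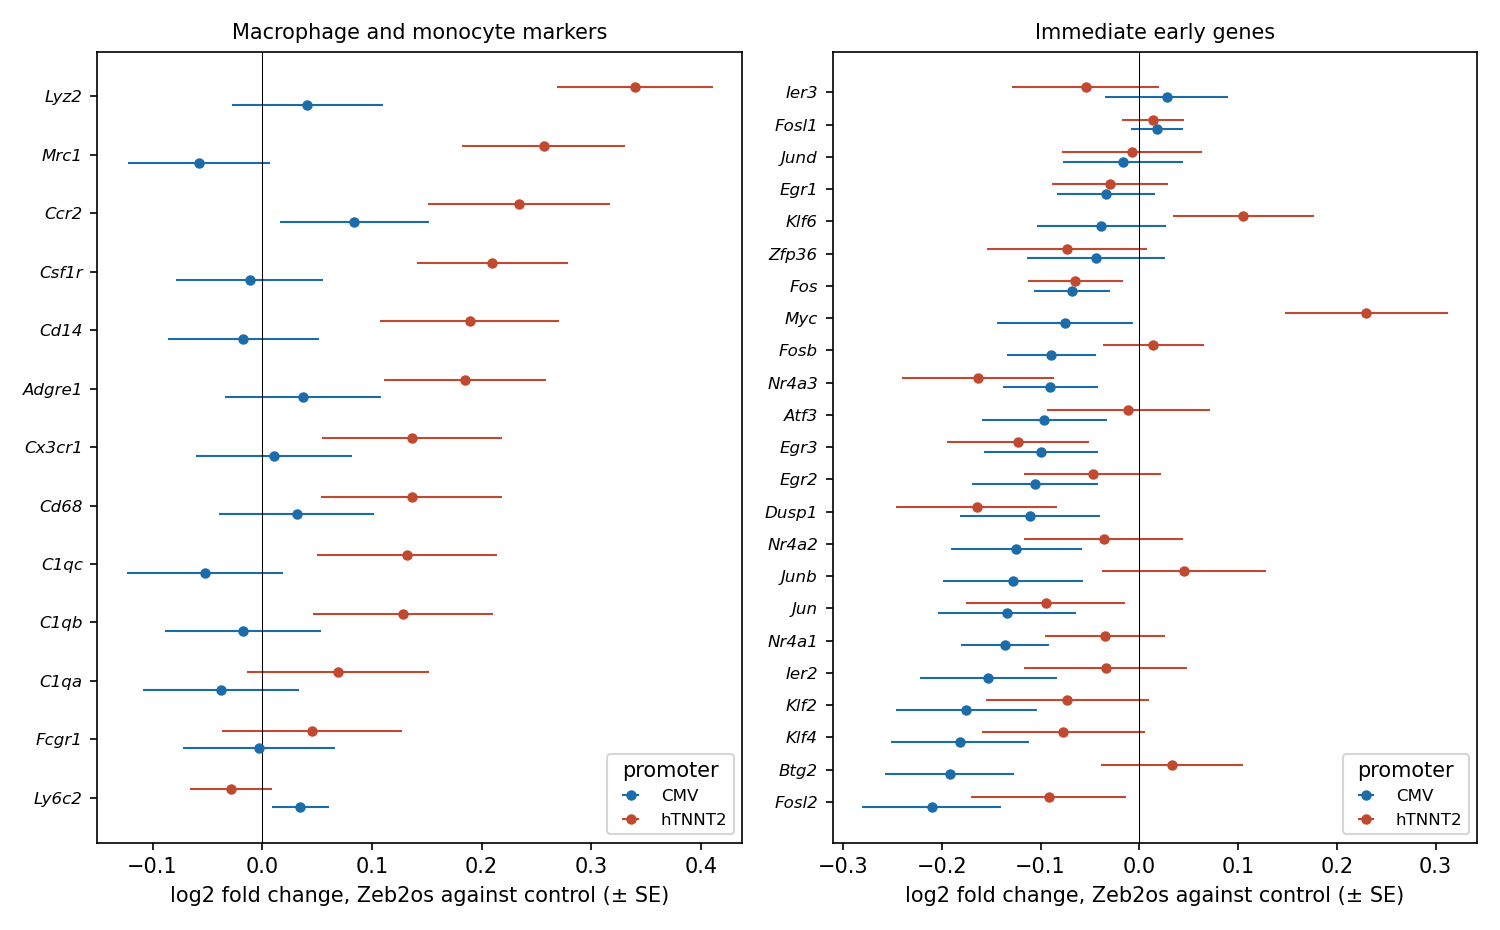
Log2 fold change of Zeb2os against control, with SE, from the authors' deposited tables (x axis) for macrophage and monocyte markers (left) and immediate early genes (right), 1 gene per row, blue for CMV and red for hTNNT2. With hTNNT2 12 of 13 macrophage markers lie above 0, and with CMV 21 of 23 immediate early genes lie below it.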

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

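The trend tests of the raised lists and of immediate early genes with transcript length and GC content were set before their results were seen. The other tests of explanations here, and the X-linked genes, were chosen only after the results were seen. The tests of the share of cardiomyocytes, of sex and of the amount of Zeb2os were first judged on the spread between genes alone. On that basis sex passed as an explanation and the others failed. For sex that pass was not clear. The signed CMV mean given below, -0.0171, had the sign that sex predicts, but with an SE of 0.0060 between genes it lay above the predicted -0.0322. The bounds were then widened after the values were seen, to let members move together as genes of the same mice do, and all 3 became undecided.

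A difference between promoters set apart 14 lists, tested on the difference of the statistics, and 1 gene, tested on the difference of the fold changes. The sex makeup of the arms differed along the same contrast and was not separable from the promoter. In the list of differences below, each value is the mean hTNNT2 log2 fold change minus the mean CMV log2 fold change over the members. It was 0.867 for Zeb2os itself in the authors' deposited tables. Above 0 lay macrophage and monocyte markers (0.153), smooth muscle and pericyte markers (0.140), extracellular matrix genes (0.101) and fibroblast markers (0.0717). Also above 0 were immediate early genes (0.0661), cell cycle genes (0.0605) and apoptosis and p53 targets (0.0594). Below 0 lay sarcomere genes (-0.104), cardiomyocyte markers (-0.0992), calcium handling genes (-0.0755) and T and NK cell markers (-0.0706). The remaining lists below 0 were nuclear respiratory chain subunits (-0.0602), B and plasma cell markers (-0.0589) and thymus markers (-0.0583). Removing the trend in mean count ended the difference for cardiomyocyte markers (adjusted p of cameraPR = 0.123), calcium handling genes (0.0560) and respiratory chain subunits (0.148). With length and GC content removed as well, those 3 lists stood at 0.244, 0.104 and 0.244, sarcomere genes at 0.0505 and apoptosis genes at 0.0528. The T and NK cell, B cell and thymus lists had too few members for that test, so 0 of the lists below 0 passed it. At a correlation of 0.05, fibroblast markers (0.0788) and apoptosis genes (0.105) did not pass.

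With hTNNT2 Zeb2os, macrophage, fibroblast and matrix genes were higher and sarcomere genes lower. A smaller share of cardiomyocytes in the tissue would raise markers of other cell types alike, and macrophage and fibroblast markers exceeded endothelial markers by a mean log2 fold change of 0.116 (23 and 12 genes), with T and NK cell markers lower at a mean of -0.045; this counts against it, but the SE of the former is 0.105 if members move together and the latter list passed under 2 of 5 alternatives, so it stays open. A trend with length and GC content is argued against for the raised lists, since all 3 passed after its removal, while a trend stays open for sarcomere genes, whose mean statistic went from -0.818 to -0.474 with mean count, length and GC content removed together (adjusted p of cameraPR = 0.177) and whose call ended with mean count alone (0.0813). The male share was 60 percentage points higher with hTNNT2 Zeb2os. If deposited fold changes scaled with the difference in male share, sex would give the members a mean CMV value of about -0.0322, signed by their hTNNT2 direction. That scaling was assumed and not tested. The members averaged -0.0171 (75 genes, SE 0.062 if members move together), so sex stays open and was not separable from Zeb2os. The unsigned CMV means were 0.0033 for macrophage markers, 0.016 for fibroblast markers, 0.00037 for matrix genes and 0.043 for sarcomere genes, so the negative average came mostly from sarcomere genes. Under the same assumed scaling, sex would give about -0.052, -0.029, -0.034 and 0.020 in turn.

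With CMV Zeb2os, immediate early genes were lower. The list passed after removal of the trend with length and GC content (p of cameraPR = 1.42e-17), which argues against that trend. If the amount of Zeb2os RNA set the fall, it should be at least as large with hTNNT2, where Zeb2os had 10.5 times the mean count. The mean Wald statistic was below 0 in both, at -0.43 with hTNNT2 and -1.57 with CMV. With hTNNT2 the list did not pass (adjusted p of cameraPR = 0.156). The fall was thus smaller there, by a mean difference of 1.14 (18 of 23 genes, sign-flip permutation test, p = 0.00042). That permutation test treats genes as independent. The list was followed up for its CMV shift, so a smaller value with hTNNT2 could come from that choice alone. Immediate early genes respond together to handling and time of sampling, and cameraPR on the difference of the statistics would lose an unadjusted p under 0.05 at a correlation of 0.20 between members, so the amount of Zeb2os cannot be told apart from variation between mice, and a different effect in other cell types reached by CMV stays open and untested.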

How the results depend on the processing

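Alternatives that remove Zeb2os or trends from the list tests, or compare Wald statistics, were chosen after the data were examined; the others were planned. In each comparison Zeb2os passed and Zeb2 did not under every gene-level alternative, and neither changed sign. The fold changes were the deposited ones in every alternative other than centring, so a sign could change there alone. Genes changed with CMV Zeb2os numbered 1. They numbered 2 at an adjusted p threshold of 0.1, with a mean count of at least 10 or at least 50, and with centring, and 13 under the empirical null. With hTNNT2 they numbered 7. They numbered 1 at a threshold of 0.01 or with a log2 fold change of at least 1, 17 at 0.1, 12 with a mean of at least 50 and 23 under the empirical null. All 7 were among the calls of every alternative other than 0.01 and the fold threshold. For the genes besides Zeb2os and Zeb2, 42 of 54 results were the same and 12 lost the call, those of the 2 stricter thresholds. Genes that differed between promoters numbered 2 at a threshold of 0.1 and 0 on the Wald scale, against 1. The Spearman correlation between tables ranged from 0.056 to 0.058. Lists shifted with CMV numbered 5, but 10 with the trend in mean count removed and 9 without Zeb2os. Lists shifted with hTNNT2 numbered 13, but 8 among genes with a mean of at least 50 and 5 with mean count, length and GC content removed. Lists differing between promoters numbered 14, 7 upward and 7 downward, but 8 with those 3 trends removed. All 8 were upward, and 6 of them were among the 14. Fewer members enter at a mean of at least 50. Removing Zeb2os left the list members as they were and took its statistic, 51.5 with CMV, out of the variance used for every list. The cause of the other moves was not tested. Other tests, normalisations and filters, pseudocounts, sex as a covariate, females only, a joint fit, leaving out each mouse, an estimated correlation and other splits of the mice all need values per mouse and were not run. No paired analysis was possible because no groups share mouse numbers and the tables hold no values per mouse.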

Other observations

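Several gene groups that the report leaves out gave little movement. Metabolic genes beyond the respiratory chain did not shift as lists. Fatty acid oxidation had an adjusted p of cameraPR of 0.520 with CMV and 0.418 with hTNNT2, and glycolysis 0.546 and 0.188. Regulators of the epithelial-mesenchymal transition, the process for which Zeb2 is best known, gave 0.546 and 0.911. In that list Vim, the intermediate filament of mesenchymal cells, stood at 0.17 (SE 0.081) with hTNNT2 in the authors' deposited table. Inflammation and chemokine genes had 13 of 20 members lower with CMV (adjusted p of cameraPR = 0.0659). The cytokine Il1b stood at -0.15 (SE 0.045) there in the authors' deposited table, and it was the single member to fall when adjusted over the list alone. Of the 5 genes with a mean count of at least 10 within 2 Mb of Zeb2os, Zeb2 included, 0 passed in either of the authors' deposited tables, and 0 had an unadjusted p under 0.05.

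Further genes with an adjusted p under 0.1 in the authors' deposited hTNNT2 table, singled out after their values were seen, included Gpx3 at 0.29 (SE 0.071) and Cp at 0.25 (SE 0.064). Dcn stood at 0.25 (SE 0.063, adjusted p = 0.0995) in the authors' deposited table. The fixed list of oxidative stress genes, to which Gpx3 belongs, did not shift with hTNNT2, with 8 members higher and 8 lower (adjusted p of cameraPR = 0.353).

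Apart from Zeb2os, the deposited fold changes of the called genes were small, and the tests of this pattern were chosen only after the values were seen. A candidate explanation is moderation of fold changes toward 0 in the authors' model. In the authors' deposited hTNNT2 table the median SE was 0.0073 for genes with a mean count under 0.5 and 0.078 for genes at 200 to 1000, whereas an unmoderated SE grows as counts fall. Xist, expressed from the inactive X of females, points the same way: the female shares of the hTNNT2 arms give an expected log2 ratio of -1.32, and the authors' deposited table lists -0.019 (SE 0.019). For the CMV arms the female shares give 0.415, and the authors' deposited table lists 0.0022 (SE 0.014). If the moderation were a normal prior, the deposited SE would allow an unmoderated value of -0.019 or -1.35 for Xist with hTNNT2. With CMV it would allow 0.0023 or 0.233, neither near the 0.415 of the female shares. For Zeb2os it would allow 6.83 to 7.89 (CMV) or 8.61 to 9.56 (hTNNT2). The printed folds may therefore understate the changes, by an amount that this prior does not settle.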
